A study of Homo sapiens with 4 samples.

How the data were processed

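RNA was profiled in CT27 cells, a human trophoblast stem cell line derived from placental cytotrophoblast, grown in stem-state conditions. One group carried a short hairpin RNA (shRNA) against PRMT1 and the other a scrambled shRNA. Per the labels' protocols, libraries from total RNA were made with the SMART-Seq v4 Ultra Low Input kit, and paired reads of 101 bp were sequenced on a NovaSeq system. The protocol also names fragmentation with adaptor ligation, and which steps applied to which library is not clear.

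The deposited count table holds whole-number counts per gene symbol, not normalized, in 4 columns. The submitters' processing notes name bcl2fastq, Subread 2.0.3, featureCounts, DESeq2 and the build hg38. The annotation release, strand setting, handling of multi-mapping reads and handling of duplicate reads are not given in the sources used here. The authors' deposited comparison table holds a baseMean signal (normalized counts averaged over the libraries), log2 fold changes with their standard errors, a test statistic (score), and p-values raw and adjusted, per the file headers and the submitters' processing notes made with DESeq2. Of the 26485 rows of the count table, 28 carried names that a spreadsheet had turned into dates and 4 shared a name with another row. These rows stayed in the library sizes and tests under the names as deposited. The kit does not mark strand as far as the sources used here say, so overlapping and antisense genes cannot be told apart, and counts of close paralogs such as the pregnancy-specific glycoproteins and the histone genes are uncertain.

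Both knockdown columns matched their samples by replicate number. The control columns carry the numbers 1 and 3, while the control samples are numbered 1 and 2. The column numbered 3 was therefore taken as a control library with no pairing, and the control libraries are called 1 and 3 here. Total counts were 19095375 and 28386708 in control libraries 1 and 3, and 11106289 and 10905183 in knockdown columns 1 and 2. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

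Columns of a group were compared with a chi-square test of their counts over genes with at least 10 counts in the pair. The knockdown columns gave 0.828 per degree of freedom over 15344 genes, against 29.7 between the controls, and a pair simulated with Poisson noise only gave 0.992. The value over all genes is drawn down by dense genes, whose knockdown counts level off (0.412 at 0.5 counts per exonic base and over). In genes under 0.05 counts per exonic base in the knockdown the value was 13.1 between the controls. Some of these genes were dense in the controls, so counts were not matched. Between the knockdown columns the value was 1.06 over 4120 genes, slightly over sampling noise. The knockdown columns were therefore summed and counted as 1 sample. This departs from the design fixed before the data were examined, which had 4 separate samples, and that fit is kept as an alternative. The fits had 3 samples and 1 residual degree of freedom, and the lone knockdown sample was assumed to vary like the controls.

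Genes were kept with filterByExpr, libraries were scaled by trimmed mean of M-values (TMM), and groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 15592 genes tested, with a threshold of 0.05, and tests were two-sided. Levels are CPM relative to the TMM-scaled library size, given for controls as mean ± SD (n = 2) and for the knockdown as 1 value (n = 1). Standard errors of log2 fold changes come from the F statistic. Where all columns of a group were at 0, a fold is a lower bound against 3 counts over that group. Where a group had 1 to 3 counts, the ratio of rates is given with its exact (Clopper-Pearson) 95% interval. Such bounds and intervals cover counting error only, since reads were not tagged by molecule.

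For 29 gene lists fixed before the data were examined, camera of limma 3.58.1 was run with a preset correlation of 0.01 on the 26 lists with at least 5 tested members. It was repeated with an estimated correlation, which here rests on 1 residual degree of freedom, and with fry. Neither called any list in any fit it was run on, not even the ribosomal proteins with all 70 members lower. A call lost in these tests therefore does not tell one list from another. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. The genes named in the text follow a rule also fixed beforehand. It takes PRMT1, then the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between groups. It adds, per list, up to 2 called genes each way with at least 1 CPM, a set of trophoblast genes, and the PRMT family. Genes named outside it are marked as chosen after their values were seen.

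Exonic length, GC content and position came from protein-coding genes of GENCODE release 29 on GRCh38, matched by symbol, which gave 85.3% of tested genes a value. The authors' build is named hg38, the same assembly. Counts per exonic base were compared between libraries. Because they leveled off in the knockdown columns, alternatives were added after seeing the data. These were only genes under 0.2 counts per exonic base, a loess offset per library on log2 counts per exonic base (the trend offset, span 0.3), the same with a further offset on GC content (the trend and GC offset, 3 rounds), 4 separate samples, list medians against each control library alone, and an estimated correlation with the trend and GC offset. The alternatives fixed beforehand were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, at least 1 CPM in 2 columns, and leaving out each column in turn. Log2 fold changes against 1 control library alone use a prior count of 2, which draws low counts toward 0, and have no test.

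The fits were tested on simulated data for 12361 genes in the comparison of knockdown and control, drawn from the control means with a seeded set of genes changed. Of 100 genes changed by 1 on the log2 scale, 43.0% were called, and of 100 changed by 2, 89.0% were called. Of 12161 unchanged genes, 21 were called. With the knockdown sample limited to 1 count per position and strand, over 12355 genes, 492 of 12155 unchanged genes were called, and 70 after the trend offset. These counts were spread evenly over positions, drawn at the knockdown's observed total, and held no GC trend. The simulation therefore does not show that the offsets remove a distortion of the size seen in the data. No column was left out.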

Results

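The transcriptome of CT27 human trophoblast stem cells was measured by RNA sequencing after knockdown of PRMT1, the main enzyme that adds asymmetric dimethyl groups to arginine, and in cells with a scrambled shRNA. The comparison asks which transcripts differ when PRMT1 is depleted in the stem state. Each group had 2 count columns. Control libraries 1 and 3 held 19095375 and 28386708 counts over 15330 and 16311 detected genes. Knockdown columns 1 and 2 held 11106289 and 10905183 counts over 18382 and 18387 detected genes. In genes under 0.05 counts per exonic base in the knockdown, the chi-square per degree of freedom was 1.06 between the knockdown columns and 13.1 between the controls. Counts were not matched in this comparison, since some of these genes were dense in the controls. The knockdown columns thus differed by about the sampling noise there and were counted as 1 sample. Knockdown values are therefore n = 1 and control values n = 2, and no spread between knockdown samples was measured.

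The groups also differed in how high counts rose. No gene of at least 500 exonic bases exceeded 2.12 counts per exonic base in a knockdown column, while ACTB, the gene of cytoplasmic actin, reached 93.1 and 142 in the controls and 1.55 in each knockdown column. In the controls, 493 and 834 genes lay above 2 counts per base, against 2 in each knockdown column. The 10 most abundant genes took 4.54% and 4.66% of control counts and 1.09% of the counts in each knockdown column. Fold changes followed this property and GC content. The median log2 fold change was 1.25 in the lowest decile of genes by CPM per kilobase and −1.16 in the highest. By GC content it was −0.30 in the lowest decile and 0.87 in the highest. Values after an offset for both trends are therefore given where the offset ended a call, turned a direction or changed a fold by more than 1.5 times. Folds given as bounds or counting ratios come from the counts and carry no offset value.

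**Figure D1:**
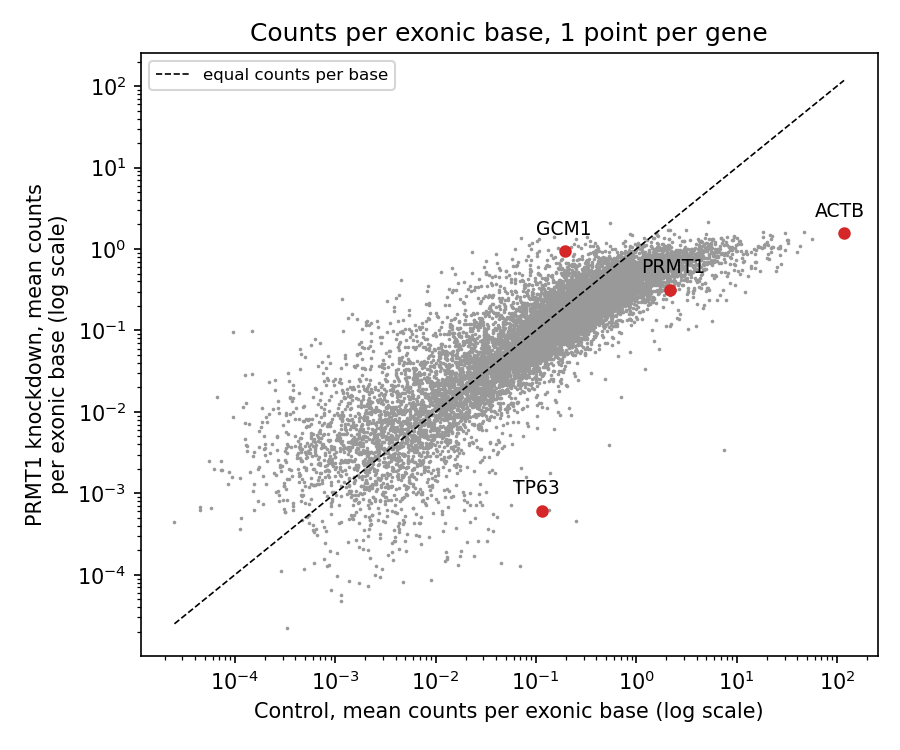
Mean counts per exonic base in the control libraries (x axis, log scale) and in the PRMT1 knockdown columns (y axis, log scale), with 1 point per gene detected in both groups and a dashed line at equal counts. ACTB lies at a mean of 117.5 counts per base in the controls and 1.55 in the knockdown, where points level off near 2.

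PRMT1 (ENSG00000126457.21; chromosome 19, 49675786 to 49689029, plus strand, GRCh38) was lower in both knockdown columns than in both controls. Its counts were 625 and 578 in knockdown columns 1 and 2, and 3207 and 5156 in control libraries 1 and 3. The level was 41.6 CPM in the knockdown and 201 ± 14.0 CPM (SD, n = 2) in the controls, a log2 fold change of −2.27 ± 0.19 (SE; edgeR quasi-likelihood adjusted p = 2.75e-04). After the trend and GC offset it was −1.70 (adjusted p = 2.49e-04). Genes of similar density also fell. Among the 500 genes nearest to PRMT1 in control counts per base the median log2 fold change was −1.22, and 23 of them, 4.60%, fell at least as far as PRMT1. Of the other arginine methyltransferases, PRMT5 was lower (log2 fold change −1.52 ± 0.18, adjusted p = 9.82e-04) and PRMT9 higher (1.05 ± 0.31, adjusted p = 0.0398) by the edgeR test. PRMT9 was not called after the trend offset (0.83, adjusted p = 0.083), by DESeq2 (1.03, adjusted p = 0.11) or among genes under 0.2 counts per exonic base (0.65, adjusted p = 0.26), but was still called after the trend and GC offset (1.09, adjusted p = 0.0312). CARM1 was lower before the offset (−0.87 ± 0.17, edgeR adjusted p = 7.92e-03) but at 0.32 after the trend offset and −0.15 after the trend and GC offset. PRMT2, PRMT3, PRMT6 and PRMT7 did not pass the threshold, with log2 fold changes of −0.07, −0.68, −0.23 and −0.13. PRMT8 was not tested. The family as a list, with 1 member higher and 3 lower of 8 both over all genes and adjusted over the list alone, was not called (camera adjusted p = 0.0576).

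Across the transcriptome, 4880 of 15592 tested genes passed the edgeR threshold, 2219 higher and 2661 lower in the knockdown. Of these, 3406 changed at least 2-fold. The share of calls that were higher was 45.5%, and it was 55.7% after the trend offset and 58.3% after the trend and GC offset. The latter called 3541 of 13301 genes, of which 2735 were also called before the offset, 2631 of them in the same direction. With 4 columns as separate samples 8625 genes passed, and among genes under 0.2 counts per exonic base 1020 of 6747 passed.

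Markers of the syncytiotrophoblast, the fused hormone-producing layer of the placenta, were higher in the knockdown. Of 41 tested, 32 rose and 3 fell, or 35 and 4 adjusted over the list alone, with a median log2 fold change of 2.68 (camera adjusted p = 7.69e-21; adjusted p = 0.554 with an estimated correlation). GCM1, the transcription factor of trophoblast fusion (chromosome 6), rose from 25.2 ± 5.83 CPM (SD, n = 2) to 179 CPM. ERVFRD-1, which encodes the fusogen syncytin-2, rose from 28.8 ± 7.50 to 218 CPM. HOPX rose from 3.92 ± 0.93 to 83.7 CPM, and PSG11, a pregnancy-specific glycoprotein, from 0.132 ± 0.102 to 8.23 CPM. Their edgeR adjusted p-values were 2.25e-04, 2.28e-04, 1.11e-04 and 3.53e-03. PSG11 was at 5.82 on the log2 scale against control library 1 alone and 4.85 against library 3 alone. After the trend and GC offset 38 of 41 markers were higher and 1 lower, with a median of 2.49. CGA, the common subunit of the glycoprotein hormones, was lower before the offset (102 against 469 ± 44.5 CPM, log2 fold change −2.20 ± 0.19) but at 0.36 after the trend and GC offset. TFPI2, a protease inhibitor, fell (−1.94 ± 0.48, edgeR adjusted p = 0.0214). CGB3 was not among the gene names of the count table.

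Markers of extravillous trophoblast, the invasive lineage, were higher in 14 and lower in 2 of 32 tested genes, or 16 and 2 adjusted over the list alone. The median log2 fold change was 0.72, also with the 3 genes at 0 in a group set at their bounds (camera adjusted p = 3.74e-04; adjusted p = 0.554 with an estimated correlation). The median was 1.06 after the trend and GC offset, with 17 higher and 1 lower. HLA-G, the class I molecule of invasive trophoblast, rose from 4.64 ± 2.44 to 69.8 CPM (log2 fold change 3.89 ± 0.41, edgeR adjusted p = 6.49e-04), and was at 4.54 against control library 1 alone and 3.38 against library 3 alone. MMP2, a gelatinase, rose from 18.1 ± 16.9 to 243 CPM (3.72 ± 0.67, edgeR adjusted p = 5.91e-03), and its log2 fold change was 5.29 against control library 1 alone and 2.95 against library 3 alone. DESeq2 did not call MMP2 (adjusted p = 0.073). PAPPA2 and TAC3 had no control counts and were at least 106-fold and 41.9-fold higher. DPP4 fell by 1.37 ± 0.17 on the log2 scale before the offset (edgeR adjusted p = 1.25e-03) and lost the call after the trend and GC offset (−0.38). TIMP3 was at −1.09 before the offset and at 1.23 after the trend and GC offset. ITGA5 did not pass the threshold (−0.39 ± 0.25), and was at 0.73 and called after the trend offset, but at 0.47 and not called after the trend and GC offset. The list of column progenitor markers was not called (camera adjusted p = 0.853), with 5 of 14 higher and 6 lower, or 5 and 7 adjusted over the list alone. HEY1 and JAG1, of the Notch pathway, rose by 4.40 ± 0.40 and 3.51 ± 0.23 on the log2 scale, NOTCH1 rose by 1.14 ± 0.18, and ITGA2 and TAGLN fell by 2.62 ± 0.22 and 2.45 ± 0.21. HEY1 was at 5.05 against control library 1 alone and 3.89 against library 3 alone. NOTCH1 lost its call after the trend and GC offset (0.40). ASCL2 was at 0.35 ± 0.24 and did not pass, and at −0.65 after the offset.

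Regulators and markers of the stem and cytotrophoblast state did not move together. Before the offset 3 of 30 were higher and 18 lower, or 4 and 18 adjusted over the list alone, with a median log2 fold change of −1.04 (camera adjusted p = 1.46e-08; adjusted p = 0.554 with an estimated correlation). After the trend and GC offset 9 were higher and 7 lower with a median of 0.026, and the list was no longer called (camera adjusted p = 0.776). TP63, the cytotrophoblast transcription factor (chromosome 3, 189631416 to 189897279), fell from 37.2 ± 7.93 CPM (SD, n = 2) to 0.278 CPM. Its log2 fold change was −7.04 ± 0.48 (edgeR adjusted p = 1.32e-04) and −7.58 after the trend and GC offset. TEAD4 fell by 1.52 ± 0.18 on the log2 scale, and ELF5 and WWTR1 rose by 2.47 ± 0.38 and 1.09 ± 0.26 (edgeR adjusted p = 1.03e-03, 3.25e-03 and 0.0194). GATA2 and GATA3 were at −1.19 and −1.29 before the offset but at 0.84 and 0.96 after the trend and GC offset. TFAP2C was at −0.14 and not called, but at 1.57 after the offset. KRT18, a dense keratin transcript, was at −4.79 and at −1.16 after the offset. CDX2 was near its detection limit, at 0.449 CPM against 0.143 ± 0.202 CPM, and was not called (log2 fold change 1.54, and −0.62 after the offset).

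**Figure D2:**
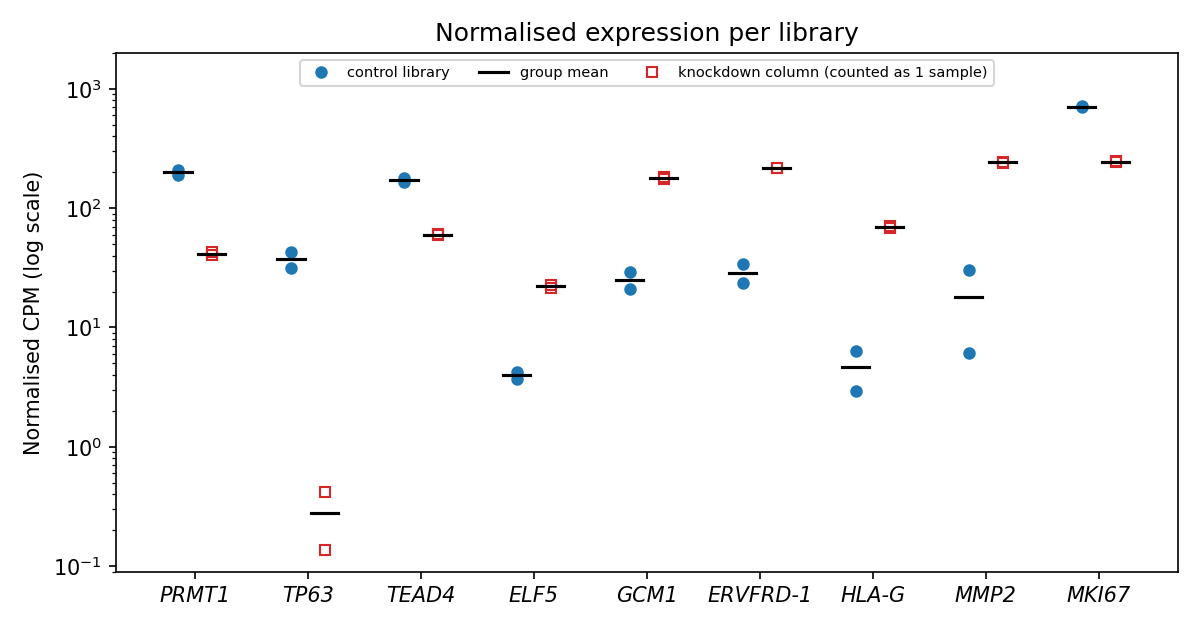
Normalised CPM (y axis, log scale) of 9 genes in each control library (filled circles) and each knockdown column (open squares, counted as 1 sample), with bars at group means. PRMT1 lies at 201 CPM in the controls and 41.6 in the knockdown, TP63 at 37.2 and 0.278, and GCM1 at 25.2 and 179.

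Cell cycle genes were lower. Of 43 S phase genes 33 fell and 0 rose (38 and 0 adjusted over the list alone), with a median log2 fold change of −0.95 (camera adjusted p = 7.45e-10; adjusted p = 0.554 with an estimated correlation). Of 54 G2 and M phase genes 48 fell and 0 rose, with the same counts adjusted over the list alone and a median of −1.34 (camera adjusted p = 3.64e-19; adjusted p = 0.554 with an estimated correlation). After the trend and GC offset the medians were −0.75 and −0.91, with 20 of 43 and 36 of 52 members lower and 0 and 2 higher. PCNA, the replication clamp, fell from 193 ± 17.2 to 33.2 CPM, and UHRF1 from 78.7 ± 14.3 to 19.1 CPM. MKI67, the gene of the proliferation marker Ki-67, fell from 711 ± 9.58 to 245 CPM (log2 fold change −1.54 ± 0.16, edgeR adjusted p = 6.58e-04). CDC20 fell from 283 ± 64.3 to 54.4 CPM. PCNA and CDC20, at −2.54 and −2.38 on the log2 scale, were at −1.37 and −1.47 after the offset. TUBB4B, at −2.60 before the offset, was at −0.36 and not called after the trend and GC offset. Targets of p53 were higher in 8 of 29 cases and lower in 5 before the offset, or 8 and 6 adjusted over the list alone, with a median of −0.020, and the list was not called (camera adjusted p = 0.826). With the trend offset 9 were higher and 0 lower, and with the trend and GC offset 8 and 1, where the median was 0.29 and the list was called higher (camera adjusted p = 0.0304; adjusted p = 0.677 with an estimated correlation), though not with the trend offset alone (median 0.22, camera adjusted p = 0.0716). The p53 median was 0.10 against control library 1 alone and −0.20 against library 3 alone. PMAIP1 and BBC3, which promote apoptosis, rose by 3.43 ± 0.50 and 2.71 ± 0.69 on the log2 scale, though BBC3 lost its call after the trend and GC offset (1.53). PMAIP1 was at 4.19 and BBC3 at 4.26 against control library 1 alone, and at 2.86 and 1.93 against library 3 alone. CDKN1A and BAX were at −1.08 and −1.29 before the offset, but at 0.26 and −0.19 after the trend and GC offset and 0.49 and 0.096 after the trend offset, with no call. Of 14 replication-dependent histone genes 3 rose and 0 fell by either adjustment, among them HIST1H1C (2.80 ± 0.40) and HIST1H2AC (2.76 ± 0.64), and the list was not called (median 1.23, camera adjusted p = 0.0801). It was called higher with 4 columns as separate samples (median 1.48, camera adjusted p = 0.049), with limma-voom (0.032), no filter (0.013) and the CPM filter (0.046).

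Interferon-stimulated genes were lower in 13 and higher in 0 of 36 tested members, or 14 and 0 adjusted over the list alone. The median log2 fold change was −1.45 (camera adjusted p = 6.15e-03; adjusted p = 0.673 with an estimated correlation), and the call was lost with 4 columns as separate samples (camera adjusted p = 0.131). The controls themselves differed, with a median 0.99 higher on the log2 scale in control library 3 than in library 1. Against control library 1 alone the median was −0.48, and against library 3 alone −2.01. EPSTI1 fell from 11.5 ± 5.40 to 0.348 CPM and OAS2 from 9.81 ± 11.7 to 0.241 CPM (edgeR adjusted p = 2.89e-03 and 0.0435). OAS2 lost its call without knockdown column 1 or 2 (adjusted p = 0.052 and 0.071), with limma-voom (0.28), upper-quartile scaling (0.062) and the CPM filter (0.072). OAS2, at −5.32 on the log2 scale and −6.37 after the trend and GC offset, was at −2.31 against control library 1 alone and −5.89 against library 3 alone. EPSTI1 was at −4.16 and −5.25 against these. NF-kappa B and inflammatory genes were higher in 5 and lower in 0 of 16 members by either adjustment, among them TNFAIP2 (3.24 ± 0.40) and RELB (2.71 ± 0.69; 1.48 and not called after the trend and GC offset). Against control libraries 1 and 3 alone TNFAIP2 was at 3.98 and 2.70 and RELB at 3.72 and 2.03. The NF-kappa B list was called (camera adjusted p = 0.0276; adjusted p = 0.554 with an estimated correlation), but not after the trend and GC offset (0.0581), with 4 columns as separate samples (0.062), among its 10 genes under 0.2 counts per exonic base (0.573) or with no filter (0.15). Its median was 0.88, and 0.59, 0.85, 0.46 and 0.85 in these. Of 18 immediate early genes 7 rose and 1 fell by either adjustment (camera adjusted p = 1.91e-03; adjusted p = 0.554 with an estimated correlation). That call was lost among the 6 immediate early genes under 0.2 counts per exonic base (camera adjusted p = 0.756) and with no filter (0.070), at medians of 0.73 and 1.06 against 0.97 over all 18. FOSB and KLF4 rose by 4.03 ± 0.24 and 2.95 ± 0.20 on the log2 scale, FOSB by 3.36 after the trend and GC offset, and DUSP6, a phosphatase of ERK, fell by 3.77 ± 0.31. Genes of the integrated stress response were higher in 9 of 30 cases and lower in 10 before the offset, or 11 and 10 adjusted over the list alone (camera adjusted p = 0.826). With the trend offset 12 were higher and 3 lower, and with the trend and GC offset 12 and 2, where the median was 0.42 and the list was called higher (camera adjusted p = 2.55e-03; adjusted p = 0.574 with an estimated correlation), against 0.12 before, −0.034 against control library 1 alone and 0.15 against library 3 alone. DDIT4 rose by 2.91 ± 0.24, FGF21 was at least 33.4-fold higher with no control counts, though not called after the trend and GC offset, and ATF5 fell by 1.91 ± 0.18. ATF4 was at −1.74 before the offset and 0.13 after the trend offset, but at −0.014 after the trend and GC offset, with no call in either.

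Genes of the translation machinery were lower. All 70 tested ribosomal protein genes, at a median of 8.09 counts per exonic base in the controls and 0.479 in the knockdown, were lower by either adjustment, with a median log2 fold change of −3.63 (camera adjusted p = 3.73e-135; adjusted p = 0.554 with an estimated correlation), and 62 were lower after the trend and GC offset with a median of −1.67. They took 4.90% and 4.18% of control counts and 0.518% and 0.521% of knockdown counts. RPLP1 and RPS24 were at 43.9 and 49.5 CPM against 1426 ± 65.6 and 1142 ± 97.3 CPM, log2 fold changes of −5.02 and −4.53, and −2.003 and −3.07 after the offset. Of 32 ribosome biogenesis genes 28 fell (30 adjusted over the list alone) and 0 rose, with a median of −1.11 (camera adjusted p = 8.75e-14, and 0.554 with an estimated correlation). After the trend and GC offset their median was −0.68 with 18 lower. NPM1 and NCL, of the nucleolus, were at −3.77 ± 0.20 and −3.35 ± 0.18, and at −1.21 and −0.61 after the offset. Nuclear genes of oxidative phosphorylation fell in 33 of 40 cases (37 adjusted over the list alone) and rose in 0. Their median was −1.31 (camera adjusted p = 1.52e-15, and 0.554 with an estimated correlation). After the offset it was −0.65 over the 35 with a matched length, of which 17 were lower. ATP5A1 and ATP5B, subunits of ATP synthase, were at −2.31 ± 0.17 and −2.29 ± 0.18, and had no matched length and so no offset value. No member of the list of mitochondrially encoded mRNAs was tested. Known substrates and RNA-binding partners of PRMT1 were higher in 3 and lower in 19 of 29 genes, or 4 and 20 adjusted over the list alone (camera adjusted p = 1.20e-09; adjusted p = 0.554 with an estimated correlation). Their median was −1.33, and after the trend and GC offset it was −0.25, with 4 of 28 higher and 11 lower, and the call was lost (camera adjusted p = 0.221). RUNX1 rose by 1.59 ± 0.23, TWIST1 was at 1.21 ± 0.35 and lost its call after the offset (0.70), and HNRNPA2B1 was at −3.16 ± 0.17, and −0.91 after the offset.

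**Figure D3:**
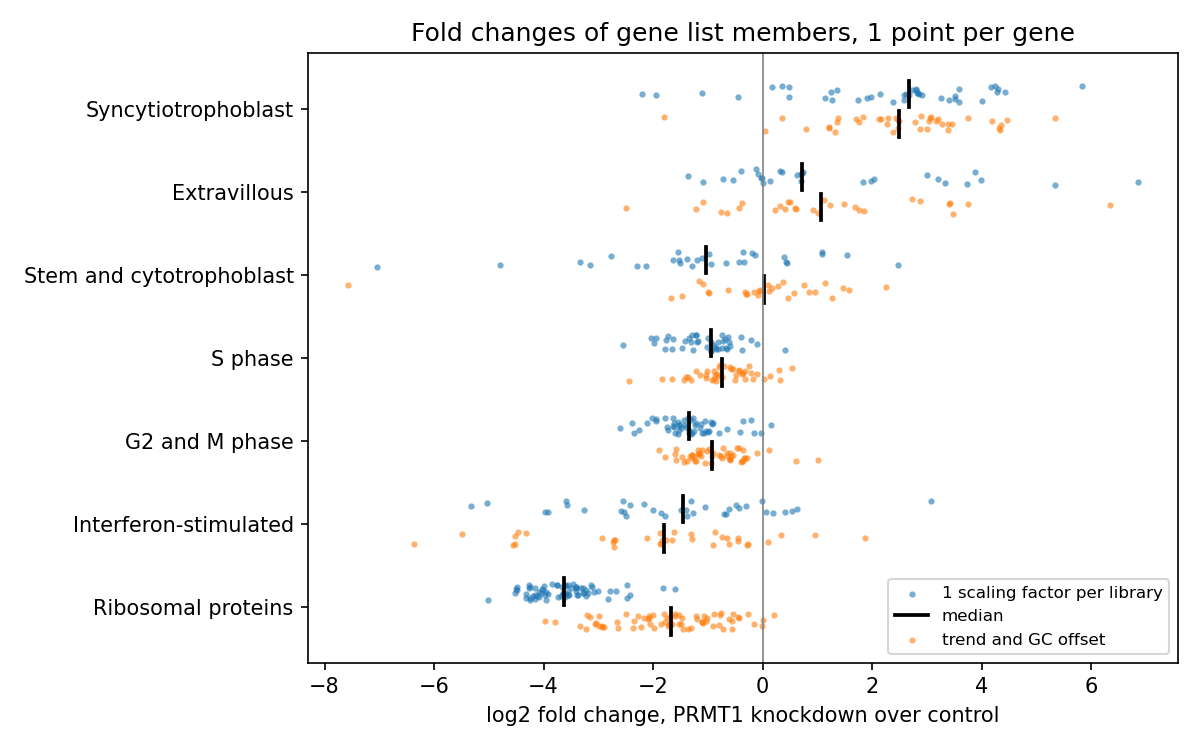
Log2 fold change of PRMT1 knockdown over control (x axis) for the members of 7 gene lists (1 point per gene), with 1 scaling factor per library (blue) and after the trend and GC offset (orange). Genes at 0 in a group are not drawn, and black bars mark the medians over all tested members. The syncytiotrophoblast medians are 2.68 and 2.49, and the stem and cytotrophoblast medians −1.04 and 0.026.

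Metabolic lists depended on the offset. Of 31 glycolysis and hypoxia genes 11 were higher and 13 lower (12 and 14 adjusted over the list alone). The list was called lower (camera adjusted p = 8.48e-03; adjusted p = 0.554 with an estimated correlation), with a median of −0.02, but its direction was higher after the trend and GC offset (0.46, with 12 higher and 9 lower, not called), and the call was lost with limma-voom (adjusted p = 0.17) and with no filter (0.12). NDRG1 and ALDOC rose by 3.92 ± 0.21 and 2.75 ± 0.62, and the dense transcripts GAPDH and ENO1 were at −4.92 ± 0.18 and −3.89 ± 0.18, and at −1.60 and −0.90 after the offset. ALDOC was at 2.10 after the offset, 3.63 against control library 1 alone and 2.13 against library 3 alone. Cholesterol biosynthesis genes were lower in 13 and higher in 0 of 24 cases (14 and 0 adjusted over the list alone), with a median of −0.81 (camera adjusted p = 1.32e-04; adjusted p = 0.554 with an estimated correlation). That call was lost after the trend and GC offset, with 6 higher and 6 lower (median 0.23, camera adjusted p = 0.779), and after the trend offset, with 4 higher and 5 lower (median −0.090). DHCR24 was at −2.07 ± 0.18 and −0.997 after the offset, and HMGCS1 was at −2.13 before the offset and 0.58 after the offset.

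Genes of epithelial-mesenchymal transition and the extracellular matrix were higher in 5 and lower in 14 of 29 cases (5 and 15 adjusted over the list alone). The median was −0.71 (camera adjusted p = 3.35e-04; adjusted p = 0.554 with an estimated correlation), and the call was lost among the 14 members under 0.2 counts per exonic base, where the median was −1.0003 (camera adjusted p = 0.183). COL1A2, a chain of type I collagen, fell from 2038 ± 596 CPM (SD, n = 2) to 1.27 CPM. It lies on chromosome 7 (94394561 to 94431232), near GNG11 (93921699 to 93928610) and TFPI2 (93885396 to 93890991), which were also lower. Whether these falls are separate changes was not tested. CDH2 fell by 4.62 ± 0.84 on the log2 scale and was at −5.61 after the trend and GC offset. COL6A3 and TWIST2 had no control counts and were at least 38.6-fold and 36.8-fold higher before the offset, but neither was called after the trend and GC offset. WNT targets (1 of 11 higher, 4 lower; 2 and 4 adjusted over the list alone) and YAP and TAZ targets (4 of 21 higher, 7 lower; 6 and 7 adjusted over the list alone) were not called as lists (camera adjusted p = 0.22 and 0.328). With the trend and GC offset the WNT list, again with 1 higher and 4 lower, was called lower (median −0.65, camera adjusted p = 0.0304; adjusted p = 0.574 with an estimated correlation; 0.126 with the trend offset alone), and 6 YAP and TAZ targets were higher and 4 lower. AXIN2 rose by 0.78 ± 0.17, TNFRSF19 fell by 3.10 ± 0.56, and CCND1 was at −2.10 and lost its call after the trend and GC offset (−0.53). GADD45B and NT5E rose by 3.80 ± 0.33 and 2.05 ± 0.53, and AXL and CYR61 fell by 3.47 ± 0.39 and 2.05 ± 0.18, and were at −4.17 and −1.22 after the offset. NT5E lost its call after the trend offset (adjusted p = 0.075), though not after the trend and GC offset (1.66, adjusted p = 0.0496), and by DESeq2 (adjusted p = 0.053). Epithelial differentiation genes were higher in 2 and lower in 4 of 14 cases (3 and 4 adjusted over the list alone) and not called as a list (median −0.44, camera adjusted p = 0.117), but called lower with 1 higher and 4 lower after the trend and GC offset (median −0.69, camera adjusted p = 0.0343; adjusted p = 0.574 with an estimated correlation; 0.115 with the trend offset alone). The median of these genes was 0.099 against control library 1 alone and −0.69 against library 3 alone. Among them KLK6 fell by 2.68 ± 0.74 (−3.40 after the offset), TGM1 was at 0.89 ± 0.26 and at 0.32 with no call after the offset, and S100A9, with 3 control counts, all in library 1, was 71.0 times higher (95% counting interval 23.8 to 348). KLK6 and S100A9 were at −1.76 and 4.30 against control library 1 alone and −3.21 and 6.10 against library 3 alone.

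Markers of other cell types were mostly low. Endothelial markers were higher in 3 and lower in 0 of 6 genes by either adjustment (camera adjusted p = 0.173), with EGFL7 at 39.0 against 7.26 ± 0.52 CPM (log2 fold change 2.42, and 1.22 after the trend and GC offset). PECAM1 was at least 36.6-fold higher with no control counts, and not called after the trend and GC offset. Of 7 fibroblast and stromal markers 2 were higher and 1, COL1A2, lower by either adjustment (camera adjusted p = 0.328), and the list's median (0.27) and mean (1.33) were above 0 while camera gave its direction as lower. With the trend and GC offset 0 of 7 were higher and 1, COL1A2 at −11.0, was lower, and camera called the list lower on a median of −0.29 (adjusted p = 0.0304; adjusted p = 0.574 with an estimated correlation; 0.0529 with the trend offset alone). The list was at 0.85 against control library 1 alone and −0.16 against library 3 alone. The immune list had 3 tested members and the pluripotency list 4, too few for a test. CD74 and CD68 rose by 2.67 ± 0.55 and 2.34 ± 0.57, and were at 1.89 and 1.67 after the offset, CD68 without a call, and DNMT3B was at −1.19 ± 0.19 and −0.25 after the offset. Of 5 amnion markers 1, HEY1, rose by either adjustment (camera adjusted p = 0.173).

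The most strongly higher genes were at or near 0 in the controls. ATOH8, SBSN, ARNT2 and PAEP had no control counts and lay at 27.8, 24.6, 23.7 and 22.4 CPM in the knockdown, at least 382-, 338-, 326- and 309-fold higher. PAEP encodes glycodelin and ATOH8 a basic helix-loop-helix factor. CX3CL1, a chemokine, ALOX15B and SHANK1 were at least 181-, 177- and 161-fold higher. CXCL12, ADRA2B and MN1 had 1 control count each and ratios of 1410 (95% counting interval 253 to 55759), 944 (169 to 37361) and 327 (58.1 to 12980). UBE2QL1 rose from 0.204 ± 0.289 to 73.0 CPM (log2 fold change 8.24, and 7.56 after the trend and GC offset), at 9.71 against control library 1 alone and 7.19 against library 3 alone, and was not called by DESeq2 (adjusted p = 0.082). Among the most strongly lower genes, DSG3, a desmosomal cadherin, had no knockdown counts and lay at 94.2 ± 17.9 CPM in the controls, at least 908-fold lower. GNG11 and CTPS2 also had no knockdown counts and were at least 182-fold and 140-fold lower. MGST1, SOX9 and PTPRD had 2, 1 and 3 knockdown counts and were 388 (95% counting interval 107 to 3208), 380 (67.9 to 15037) and 223 (76.2 to 1086) times lower. GNG11 and PTPRD were at −8.21 and −7.44 on the log2 scale against control library 1 alone and −7.36 and −6.57 against library 3 alone. MAGEA4, HACD4 and EMB fell by 6.41 ± 1.07, 6.10 ± 1.00 and 5.81 ± 0.47 on the log2 scale. MAGEA4 lay at 20.2 and 86.3 CPM in control libraries 1 and 3, with log2 fold changes of −4.84 and −7.01 against each alone. HACD4 was at −6.24 and −4.71 against these and at −7.12 after the trend and GC offset. With limma-voom GNG11, PTPRD, MAGEA4 and HACD4 were not called (adjusted p = 0.056, 0.063, 0.13 and 0.11). ACTB was at −5.72 before the offset and at −0.95 after the trend and GC offset.

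In the authors' deposited table, 7848 of 16439 genes had an adjusted p under 0.05, 3928 higher and 3920 lower. Of the 15569 genes in both analyses, 4858 were called in both, all in the same direction, where independent lists of these sizes would share 2447. The log2 fold change of PRMT1 in the authors' deposited table was −2.29 with a standard error of 0.14. Both analyses rest on the same counts, so an overlap above that of independent lists is no separate support for the calls.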

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

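The trend offsets, the density limit, the separate columns, the single-control medians and the estimated correlation with an offset were chosen after seeing the data, and the other alternatives before the data were examined. No paired analysis was possible because the knockdown columns counted as 1 sample and the control columns carry the numbers 1 and 3, so the groups share fewer than 2 numbers. Leaving out a control leaves no residual degree of freedom, so those values have no test or count of calls. Median-of-ratios scaling kept direction and side of the threshold for all 112 other named genes and 26 lists, upper-quartile scaling for 110 and 26, limma-voom for 107 and 22, and DESeq2 for 104 of the 111 genes to which it gave an adjusted p.

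The count of 4880 genes became 8625 with 4 columns as separate samples and 1020 under 0.2 counts per exonic base, where fewer genes were tested. The 3406 genes changed at least 2-fold became 906 under that limit and 2118 after the trend and GC offset. Without a knockdown column these counts were 4733 to 4802 and 3333 to 3408. PRMT1 ranged from −2.40 to −2.19 over the left-out libraries.

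The stem and cytotrophoblast list lost its call under the density limit (median 0.69), the trend offset (−0.020), the trend and GC offset (0.026), and with an estimated correlation or fry (−1.04 in both), and ranged from −1.25 to −0.92 over the left-out libraries. The syncytiotrophoblast list lost it under the density limit, with 6 members left (2.31). Estimated correlation and fry use the main medians and ended the calls of that list (2.68), the extravillous list (0.72), S phase (−0.95), G2 and M phase (−1.34) and interferon-stimulated genes (−1.45). The last also lost its call with 4 separate columns (−1.41) and ranged from −2.01 to −0.48 over the left-out libraries, the nearest to 0 without control library 3. Column progenitor markers ranged from −1.17 to −0.89. Apart from estimated correlation and fry, other called lists lost their call as follows. NF-kappa B genes (0.88) did so with 4 columns (0.85), the density limit (0.46), no filter (0.85) and the trend and GC offset (0.59). Immediate early genes (0.97) did so with the density limit (0.73) and no filter (1.06), and the matrix list (−0.71) with the density limit (−1.0003). Glycolysis genes (−0.020) did so with limma-voom (−0.022) and no filter (−0.17). Cholesterol genes (−0.81) did so after the trend offset (−0.090) and the trend and GC offset (0.23), and PRMT1 substrates (−1.33) after the latter (−0.25). The density limit leaves fewer members. Of 112 other named genes, 49 moved by more than 1 SD of the controls against control library 3 alone and 31 against library 1 alone. FGF21, TWIST1 and TWIST2 lost their calls without knockdown column 2. DESeq2 ended the calls of UBE2QL1, BBC3, PRMT9, TWIST1, NT5E, TGM1 and MMP2, and the density limit those of WWTR1, FGF21, PRMT9, TWIST1, COL6A3, TWIST2, NT5E, RELB, PECAM1 and CD68.

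Signs reversed after the trend offset for TIMP3 (1.04), BAX (0.096), CDKN1A (0.49), ATF4 (0.13), HMGCS1 (0.081), GATA2 (1.17), GATA3 (0.98), TFAP2C (1.47), CDX2 (−0.53), ITGA5 (0.73), CARM1 (0.32) and the glycolysis and hypoxia list (0.52). After the trend and GC offset they reversed for CGA (0.36), TIMP3 (1.23), CDKN1A (0.26), HMGCS1 (0.58), GATA2 (0.84), GATA3 (0.96), TFAP2C (1.57), CDX2 (−0.62), ITGA5 (0.47), ASCL2 (−0.65) and the glycolysis list (0.46), which also reversed under the density limit (1.41) and ranged from −0.11 to 0.014 over the left-out libraries, reversed without control library 3. The medians of other lists turned as well, stem and cytotrophoblast (0.026 after the trend and GC offset), cholesterol (0.23), p53 (0.29), fibroblast (−0.29) and amnion (−0.41) genes there, p53 (0.22), YAP and TAZ (0.070) and fibroblast (−0.76) genes after the trend offset, p53 and glycolysis genes with upper-quartile scaling (0.073 in both), p53, stress response and epithelial differentiation genes without control library 3, and fibroblast markers without library 1. PRMT2 reversed with upper-quartile scaling (0.023) and without control library 1 (0.068). Among lists not called, the direction given by camera turned for p53 targets with no filter (median −0.012) and 4 columns (−0.047), for stress response genes with no filter (0.15), 4 columns (0.095) and limma-voom (0.15), for fibroblast markers with no filter (0.17), limma-voom (0.31) and the density limit (1.61), and for epithelial differentiation genes under that limit (1.48). The offset's construction, which removes the fall of dense genes, moves most of these genes up; beyond that the cause was not tested. The lists of p53 targets, stress response genes, WNT targets, epithelial differentiation genes and fibroblast markers, not called before the offset, were called after the trend and GC offset (camera adjusted p = 0.0304, 2.55e-03, 0.0304, 0.0343 and 0.0304), but none with an estimated correlation (0.574 to 0.677), and with the trend offset alone only the stress response genes were (1.45e-03, against 0.0716, 0.126, 0.115 and 0.0529 for the others). ASCL2 and PRMT3 were called with 4 columns. Depth limits genes at 0 in a group to bounds.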

Other observations

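All tests in this part were chosen after the results were seen, and so were the gene families and single genes named here. Within the syncytiotrophoblast list, and so already in its counts, all 9 tested pregnancy-specific glycoprotein genes rose, both before and after the trend and GC offset, though reads can be shared between these close paralogs. PSG7, outside the list, was the 1 tested member of the family not called. LGALS13, LGALS16 and LEP also belong to that list. The galectins, placental and other, went both ways, with 3 of 8 higher and 2, LGALS1 and LGALS3, lower, or 3 and 1 after the offset, and LGALS13 and LGALS16 rose from 1.70 ± 0.48 to 32.8 CPM and from 6.91 ± 2.63 to 50.3 CPM. The inhibitor of differentiation genes ID1, ID2, ID3 and ID4 rose before the offset, 3 of 4 after it, and all 3 NR4A nuclear receptor genes, of which NR4A1 is in the immediate early list, rose in both. LEP, the leptin gene, lay at 312 CPM against 3.15 and 28.0 CPM in control libraries 1 and 3.

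Of 5 tested desmosomal cadherin genes all fell before and 4 after the trend and GC offset, where DSG2 lost its call. DSG3 and DSC2 are in the epithelial differentiation list. DSG3 lies on chromosome 18 (31447795 to 31478702), as does CDH2 (27950966 to 28177446), which was also lower. Whether the falls of these cadherin genes are separate changes was not tested. DSC3 fell from 255 ± 90.9 to 7.54 CPM. Among 20 tested chemokine and chemokine receptor genes 9 rose and 0 fell, with the same counts after the offset. CCR7 rose from 1.69 ± 0.55 to 101 CPM and ACKR3, a scavenging receptor of CXCL12, from 0.427 ± 0.435 to 63.2 CPM. The log2 fold change of ACKR3 was 8.26 against control library 1 alone and 6.23 against library 3 alone. MAGE genes of families A, B and C went both ways, 2 higher and 2 lower of 11. Of 10164 genes with at least 100 counts in both controls, 5 had none in either knockdown column, and 8 of 10651 showed the opposite.

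Genes of high density, the ribosomal proteins among them, were lower in the knockdown, and lower depth is argued against as the cause, since depth leaves a gene group's share of counts in place while the ribosomal proteins took at most 0.521% of counts in a knockdown column and at least 4.18% in a control. Between the knockdown columns the chi-square per degree of freedom was 0.412 in genes of at least 0.5 counts per exonic base and 1.06 in genes under 0.05, so dense genes varied less than Poisson counts do. A limit on counts per position in the knockdown columns, as removal of duplicate reads by position would leave, is a candidate explanation, and why it would apply to these columns alone stays open. A true fall in ribosomal protein mRNAs cannot be told apart from such a limit, since counts leveled off in both knockdown columns and in neither control. More knockdown samples that level off in the same way would not separate them. Their median stayed at −1.67 after the trend and GC offset. ACTB, KRT18, GAPDH and ENO1, at 22.8 counts per exonic base or more in the controls, also stayed low after it (−0.95, −1.16, −1.60 and −0.90). The offset may thus remove too little at high density, so the ribosomal median does not argue against these trends as the whole of that fall. Exonic length also counts all annotated exons and can understate how densely short mRNAs were read.

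The median of the syncytiotrophoblast markers stayed at 2.49 after the trend and GC offset. The trends as fitted therefore do not account for the rise, though how far the offset removes the distortion is not shown. Among the 6 markers under 0.2 counts per exonic base the median was 2.31, but the list was not called there (camera adjusted p = 0.0607). The list differed by a median of 0.15 on the log2 scale between the control libraries, but a difference between cultures other than PRMT1 cannot be told apart from the knockdown on 1 sample. A shift from cycling stem cells toward syncytiotrophoblast with PRMT1 depletion is a hypothesis with which the lower G2 and M phase genes (median −0.91 after the offset) would be in line, and it stays open until several separate knockdown cultures are compared. The rise is not specific to syncytiotrophoblast, since extravillous markers also rose after the offset (17 higher and 1 lower of 32, median 1.06; HLA-G at 3.47 and ADAM12 at 6.34). The stem and cytotrophoblast list was not called after the offset (median 0.026), with TP63 at −7.58 and ELF5 at 2.26, so a general loss of stem markers is not shown.

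The median of the interferon-stimulated genes stayed at −1.80 after the trend and GC offset. The trends as fitted therefore do not account for their fall, with the same limit on what the offset removes. Whether a high level in control library 3 alone accounts for the fall stays open. Against control library 1 alone the median was −0.48, less than the 0.99 by which the list differed between the control libraries, and against library 3 alone it was −2.01. An effect of PRMT1 on these transcripts cannot be told apart from a difference between cultures with 1 knockdown sample and 2 controls this far apart.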
